A study of Mus musculus with 12 samples.

How the data were processed

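Gene expression was measured in the lungs of 12 mice on Affymetrix Mouse Gene 2.0 ST arrays, with 1 array per mouse and 3 mice in each of 4 groups, per the labels. Mice were sensitised to ovalbumin (OVA, an egg protein used to provoke allergic airway inflammation) by injection of 10 µg with alum on days 5 and 7 of life and challenged with a 3% OVA aerosol for 15 min a day on days 9 to 11, 24 to 26 and 37 to 39, or received buffer (phosphate-buffered saline). They breathed concentrated ambient fine particles (PM2.5) at a target of 600 µg per cubic metre for 1 h a day, or filtered air, from day 5 to day 39, and lungs were taken on day 40. The control group received buffer and filtered air. Total RNA (100 ng) was amplified and labelled with biotin, per the labels' protocols.

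The deposited table holds log2 expression values for 41345 probe sets on 12 arrays. Robust multi-array average (RMA), Transcriptome Analysis Console and R 4.0.2 are named in the submitters' processing notes, which give no role or order for them. RMA subtracts background, equalises the distribution of intensities between arrays and summarises the probes of a probe set on the log2 scale, so absolute differences in total RNA between lungs are not visible in such values and changes near the background are compressed. The deposited log2 values ran from 1.15 to 14.1, no value was missing, and array medians lay between 6.41 and 6.55. The genome build behind the probe sets was not given in the sources used here, and no coordinates are printed. Precision is limited by the number of arrays, 3 per group. The table gives no detection call or background level per probe set, so a low value cannot be told from background.

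Probe sets were named from the platform annotation. Of them, 23521 had 1 gene symbol, 1814 had several and 16010 had none here, 190 of the last being control probe sets. Entrez identifiers of 23328 of the probe sets with 1 symbol were in the RefSeq gene table of assembly GRCm38.p6, and 0 of those symbols differed. Only probe sets with 1 symbol were tested. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays was used, which left 22180 genes.

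From these values, linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, without trend and not robust) to all 12 arrays as 4 group means with 8 residual degrees of freedom. There were 8 contrasts: OVA, PM2.5 and OVA+PM2.5 each against control, OVA+PM2.5 against OVA and against PM2.5, the interaction of OVA and PM2.5, and the average effect of each exposure over both levels of the other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. In total, 41 gene lists covering airway inflammation, lung cell types, responses to particles and tissues that can be carried over in dissection were fixed before the data were examined. They hold 783 distinct genes, of which 712 were measured, with 7 to 33 measured genes in a list. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 41 lists within a contrast, and called at an adjusted p under 0.05. Within a list, members were also adjusted over the list alone. Verbs of change below refer to the list test at the preset correlation or to members past the test adjusted over the list alone.

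Named genes followed a rule fixed before the data were examined. For the 3 comparisons against control it took 10 genes per direction, and for the other 5 it took 5, first among called genes whose groups did not overlap. Open places were filled with the genes of smallest unadjusted p among those without overlap and with an absolute log2 fold change of at least 0.585, given as values that did not pass the test. Predicted genes, olfactory and vomeronasal receptors and small RNAs were left out of that rule. In the comparisons of 3 arrays against 3, 8.63% to 13.5% of all genes had no overlap, where 10% are expected by chance. Lack of overlap alone is therefore little evidence. Up to 4 members of each list with the smallest p, and each member past the test adjusted over the list alone, could also be named. Of the named genes, Nrxn2 had 2 probe sets that differed in OVA against control, with log2 fold changes of -0.63 and -0.04.

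The procedure was tested on simulated data for OVA against control, with 22180 genes drawn independently at their own means and residual spreads and 200 of them changed. It called 80% of genes changed by 1 log2 unit, 97% of those changed by 2 and 99.5% of those changed by 4. Among unchanged genes it called 6, 8 and 12 in these runs. With no gene changed it called 0 genes and 0 of 41 lists. The simulated genes were independent, so this says nothing of lists whose genes vary together between animals. Each changed gene was also moved by the same amount on all 3 OVA arrays. Real response genes could vary widely between animals: Clca1, with an SD of 1.79 on the OVA arrays, was not called by limma at 5.35 (adjusted p = 0.63). The shares recovered therefore do not apply to such genes.

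The replicate numbers come from the sample titles, and no label links a number to an animal, litter, batch or day. Deviations from the group means were correlated between same-numbered arrays of each pair of groups. For OVA and OVA+PM2.5 all 3 pairs had r over 0.1 (0.17 to 0.37), against -0.20 to -0.00056 for arrays of different numbers. Centring on group means pushes the latter towards negative values where the former are positive, so they are no separate evidence. The main fits and list tests took no account of the numbers and treated these arrays as unpaired. Only alternative fits with a block and some permutations and split counts treated the numbers as pairing the arrays of these groups. These correlations do not establish such a pairing. In each of the other 5 pairs of groups at least 1 of the 3 pairs had r at or below 0.1, so no number was taken to pair arrays there.

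Alternatives covered the genes with the higher mean values, quantile normalization, centring on array medians, eBayes with trend and robust, array weights, fits to the compared groups alone, all probe sets, averaged probe sets, the replicate number as a block, other thresholds, the list test with an estimated correlation, the rotation test fry, and each array left out. Alternatives added after the data were examined left out 3 arrays with transcripts of squamous epithelium, took those transcripts as a covariate, took Xist as a covariate, or fitted the OVA and OVA+PM2.5 arrays alone with the replicate number as a block. Leaving out the 3 arrays leaves 2 control arrays and 1 PM2.5 array, whose spread is then taken from the other groups. Figures were drawn with matplotlib 3.10.9.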

Results

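Lungs of 12 BALB/c mice at day 40 of life were compared on expression arrays, 3 animals per group. The groups were control, OVA (ovalbumin sensitisation and challenge), PM2.5 (concentrated ambient fine particles) and OVA+PM2.5, so that each exposure was measured alone and together with the other. Values are log2 RMA values, changes are log2 fold changes with their standard error (SE) from limma, and n = 3 in each group throughout. Pairs of arrays correlated at 0.972 to 0.990 across all probe sets other than control probe sets, and 0 arrays held values identical to another.

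Control 3, PM2.5 2 and PM2.5 3 stood apart from the other 9 arrays along the first principal component, which held 43.0% of the variance. Krt4, a keratin of stratified squamous epithelium, read 13.4, 11.6 and 13.5 on them and 5.45 to 6.18 on the others. Acta1, skeletal muscle actin, read 13.2, 12.9 and 13.2 on these 3 arrays and 7.24 to 9.32 on the others. Xist, transcribed from the inactive X chromosome of female cells, read 11.7 to 12.1 on 5 arrays (control 2, OVA 2, PM2.5 3, OVA+PM2.5 2 and OVA+PM2.5 3) and 5.02 to 6.18 on the other 7, although the labels describe male mice. The mean of the Y-linked genes Eif2s3y, Uty and Kdm5d was 4.15 to 4.72 on those 5 arrays and 6.23 to 9.27 on the 7, the lowest of them being control 1.

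**Figure D1:**
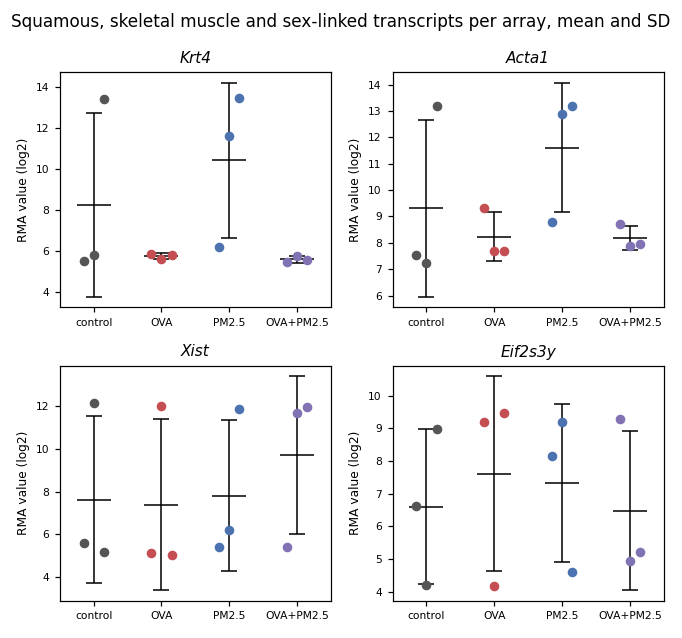
Values of Krt4, Acta1, Xist and Eif2s3y in log2 units (vertical axes) on each array by group (horizontal axes); points are arrays, bars the group mean and SD, n = 3. Krt4 lies above 11 on 1 control and 2 PM2.5 arrays. Xist lies above 11 on 5 arrays: control 2, OVA 2, PM2.5 3, OVA+PM2.5 2 and OVA+PM2.5 3.

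OVA against control asked what allergic sensitisation and challenge did in filtered air. Large differences were seen in genes of mucus and of alternatively activated macrophages. Clca1, a protein secreted by goblet cells, was 5.35 (SE 1.01) higher on the log2 scale, or 40.9-fold, and Retnla, a secreted product of alternatively activated macrophages and airway epithelium, was 3.80 (SE 0.57) higher. Goblet cell and mucus genes rose as a group: all 18 measured members had higher means, with a median of 0.93, and 8 passed the test adjusted over the list alone against 0 over all genes (camera adjusted p = 1.47e-14, adjusted p = 0.56 with an estimated correlation). Those 8 included the gel-forming mucin Muc5ac (3.04, SE 0.88), Tff2 (1.87, SE 0.61), Fcgbp (2.35, SE 0.88) and the goblet cell transcription factor Foxa3 (0.57, SE 0.19). Of the 8, 6 passed without control 2 and only Clca1 without control 1, control 3, OVA 1 or OVA 2. Alternative macrophage activation genes rose, 16 of 16 higher with a median of 0.76, and of them Retnla passed adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). Without OVA 2 the median of this list was 0.21, with the call kept.

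Inflammatory cytokine and NF-kB target genes rose in OVA lungs, with 25 of 25 higher and a median of 0.74, which was 0.13 and no longer called without OVA 2 and 1.13 without OVA 3. Interferon-stimulated genes rose, with 23 of 24 higher and a median of 0.43 (adjusted p = 0.56 with an estimated correlation for both lists). The chemokines Cxcl10 (0.92, SE 0.14) and Cxcl9 (1.29, SE 0.32) were the 1 member of each that passed adjusted over the list alone, and Cxcl9 no longer did without control 1, control 2 or OVA 1. Cell cycle genes rose, 29 of 29 higher with a median of 0.35, among them Top2a at 0.65 (SE 0.22) and Mki67 at 0.63 (SE 0.21), of which 0 passed over the list alone (adjusted p = 0.56 with an estimated correlation). Type 2 cytokine and chemokine genes rose, 16 of 19 higher with a median of 0.29. Il4 read 0.67 (SE 0.20), Il13 0.84 (SE 0.36) and Ccl22 1.27 (SE 0.45), and 0 members passed over the list alone (adjusted p = 0.56 with an estimated correlation). Without OVA 2, Il4, Il13 and Ccl22 read 0.40, 0.31 and 0.58. Eosinophil markers (median 0.48), dendritic cell and MHC class II genes (median 0.32), macrophage markers (median 0.32) and erythroid markers (median 0.18) rose, each with an adjusted p = 0.56 with an estimated correlation. Without OVA 2 the type 2 and eosinophil calls were lost, at medians of 0.04 and 0.10, and without control 2 or OVA 1 the erythroid call, at 0.19 and 0.17. Calls were kept at other sizes for interferon-stimulated genes without OVA 1 (0.12), cell cycle genes without control 3 (0.24), type 2 genes without OVA 3 (0.68) and MHC class II genes without OVA 2 or OVA 3 (0.18 and 0.49).

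Neutrophil markers (median 0.47), matrix proteases and inhibitors (median 0.09) and complement and coagulation genes (median 0.10) rose, each with an adjusted p = 0.61 with an estimated correlation. Ciliated cell markers (median 0.24) and surfactant genes (median 0.06) rose, both with an adjusted p = 0.78 with an estimated correlation, and T cell markers (median 0.14) rose with an adjusted p = 0.93 with an estimated correlation. Endothelial markers fell, 18 of 21 lower with a median of -0.14, and adipose markers fell, 14 of 14 lower with a median of -0.84 (adjusted p = 0.61 with an estimated correlation for both). Senescence genes fell with a median of -0.13, Igfbp3 passing adjusted over the list alone at -0.81 (SE 0.22), or -0.54 without OVA 2, and without any 1 array other than OVA 3 not passing (adjusted p = 0.56 with an estimated correlation). Skeletal muscle markers (median -1.70) and oxidative phosphorylation genes (median -0.15) fell, with adjusted p = 0.77 and adjusted p = 0.78 with an estimated correlation. Without control 3, 1 of the 3 arrays with squamous transcripts, these last medians were 0.07 and 0.029 and the T cell median was -0.0028. Of the 21 calls, 7 held whichever array was left out: goblet, alternative macrophage, neutrophil, macrophage, MHC class II, cell cycle and interferon-stimulated genes. Some lists share members, so these calls are not independent. Chil3, Mrc1, Marco and Itgax are on both the alternative macrophage and the macrophage list, and Cd209a on the former and the MHC class II list. Further calls were lost for T cells without OVA 1 (0.08) or OVA 2 (0.02), surfactant genes without control 1, control 3, OVA 1 or OVA 2 (0.02 to 0.05) and ciliated cells without control 1, control 3 or OVA 1 (0.08 to 0.15). Endothelial and senescence calls were lost without control 1 (-0.07 and -0.0086), and also without OVA 1 (-0.08) and OVA 3 (-0.12), respectively. Protease and complement calls were lost without control 2 (0.08 and 0.17) or OVA 2 (0.04 and 0.08), the adipose call without control 3 (-0.37) or OVA 3 (-0.39), and the oxidative phosphorylation call without OVA 3 (-0.12). Medians kept the call but moved by over 1.5 times for neutrophil (0.28) and complement lists (0.18) without OVA 1, and for T cell markers without control 1 (0.28) or OVA 3 (0.35). The same holds for oxidative phosphorylation without control 1 or control 2 (-0.25 and -0.23), skeletal muscle without control 1 (-2.60), surfactant (0.09) and ciliated lists (0.45) without control 2 and endothelial markers without control 3 (-0.22).

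Among the other named genes of OVA against control, Vnn1, Clec4a1, Ms4a6c, Calhm6, Lpxn and Htr2a read 0.63 to 1.11 higher, and Mcpt4, a mast cell protease, read -1.32 (SE 0.24). Mast cell markers were not called as a list, but adjusted over that list alone Mcpt4 fell and Il4 rose, the latter not without control 1, control 2, control 3 or OVA 2. Vtn, Ms4a4d, Otc, Abca8b, Nrxn2, Eya4, Colgalt2 and Arhgap20 read -0.59 to -1.19, of which Otc read -0.47 without control 3 and Abca8b -0.40 without OVA 2. Over 22180 genes limma called 0 genes, with a smallest adjusted p of 0.54 against 1363 genes at an unadjusted p under 0.05, where 1109 are expected by chance. The count was 0 as well with trend and robust eBayes and with array weights, and 1 gene, Junos, named here after its values were seen, passed when OVA 2 was left out (1.07, SE 0.10, against 0.74 with all arrays).

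**Figure D2:**
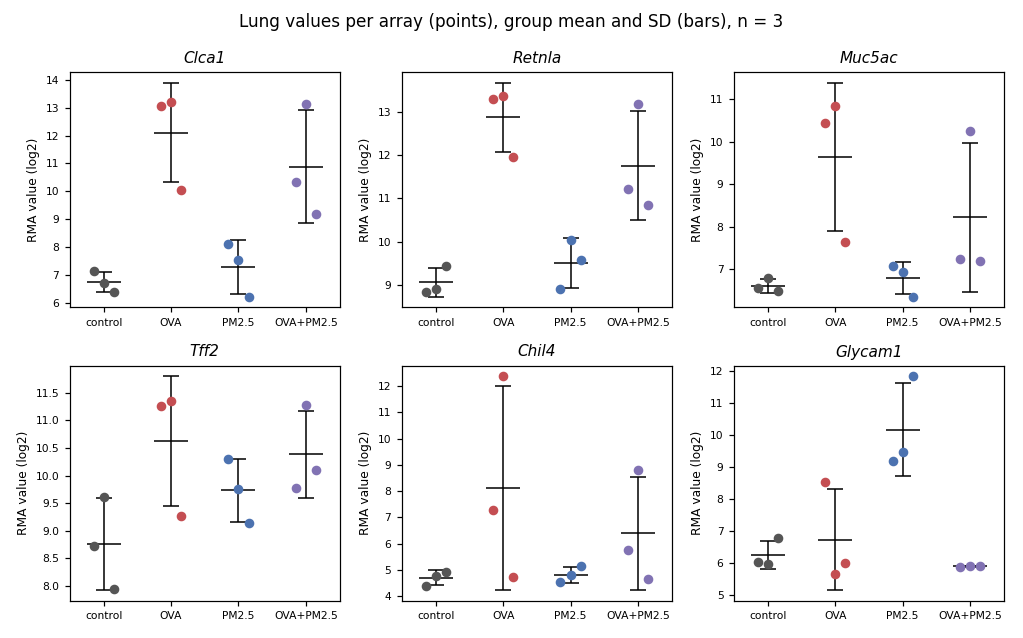
Values of Clca1, Retnla, Muc5ac, Tff2, Chil4 and Glycam1 in log2 units (vertical axes) on each array by group (horizontal axes); points are arrays, bars the group mean and SD, n = 3. Clca1 lies between 10.0 and 13.2 on the OVA arrays and between 6.41 and 7.14 on the control arrays, while Chil4 reaches 12.4 on OVA 2 and 4.72 on OVA 3.

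PM2.5 against control asked what particles did without sensitisation. Glycam1, a mucin-like ligand made by high endothelial venules, was 3.90 (SE 0.77) higher, or 15.0-fold. Timd4 (0.85, SE 0.21) and Cd209b (0.82, SE 0.22), both macrophage receptors, and Pla2g2d (0.75, SE 0.16), a phospholipase of lymphoid organs, were also higher. Alveolar and interstitial macrophage markers were not called as a list (11 of 19 higher, median 0.019, adjusted p = 0.50). Clock genes moved apart within their list, which fell as a whole with a median of -0.32 over 16 genes (camera adjusted p = 0.012, adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 7 members passed against 0 over all genes: Npas2 (1.17, SE 0.33) and Arntl (0.72, SE 0.26) rose, and Dbp (-1.51, SE 0.47), Per1 (-0.83, SE 0.26), Per3 (-0.80, SE 0.25), Nr1d1 (-0.64, SE 0.18) and Nr1d2 (-0.70, SE 0.23) fell. Npas2 and Arntl are activators of the clock and the other 5 are among their targets. Without the 3 arrays with squamous transcripts the clock list's median was -0.22 and the call was lost, with 1 PM2.5 array left against 2 controls. Without them, Npas2 read 0.61, Arntl 0.30, Dbp -0.62, Per3 -0.46, Nr1d1 -0.42 and Nr1d2 -0.26 in PM2.5 against control, and Per3 read -0.52 without PM2.5 3. Of the 7 members, 0 passed over the list alone without control 1, control 3, PM2.5 2, PM2.5 3 or the 3 arrays, and 5 without control 2. All 7 passed without PM2.5 1, and with the squamous list as a covariate 5 did, Arntl and Nr1d2 not.

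Cardiac muscle markers rose in PM2.5 lungs, 17 of 17 higher with a median of 0.77, with Nppa at 3.28 (SE 1.25) and Myl4 at 0.65 (SE 0.24), and 0 passed over the list alone (adjusted p = 0.51 with an estimated correlation). The list mean was 9.44, 10.1 and 9.38 on PM2.5 1, PM2.5 2 and PM2.5 3, and 8.31 to 8.95 on the controls. It was also 9.52 on OVA 1 and 9.54 on OVA+PM2.5 1, and 7.80 to 8.79 on the other OVA and OVA+PM2.5 arrays. Cardiac muscle can be carried over in dissection, and these values do not separate that from an effect of particles. B and plasma cell markers rose, 17 of 18 higher with a median of 0.22, with Cd79b at 0.34 (SE 0.09), and erythroid markers rose with a median of 0.20 (adjusted p = 0.51 with an estimated correlation for both). Heat shock and unfolded protein response genes (median 0.21), antioxidant and NRF2 target genes (median 0.09) and club cell markers (median 0.09) rose, each with an adjusted p = 0.65 with an estimated correlation. Gsta4, a glutathione transferase, read 0.39 (SE 0.12) higher, or 0.25 without control 1. Ribosomal protein genes (median 0.04) and cholesterol synthesis genes (median 0.05) rose, both with an adjusted p = 0.89 with an estimated correlation. Skeletal muscle (median 1.34), cell cycle (median 0.14), ciliated (median 0.15) and mesothelial lists (median 0.13) rose, each with an adjusted p = 0.92 with an estimated correlation, and the arrays high in Acta1 are control 3, PM2.5 2 and PM2.5 3, on both sides of this comparison. Without the 3 arrays with squamous transcripts cell cycle genes were called in the opposite direction (median -0.23, adjusted p = 4.38e-06), a call that rests on 1 PM2.5 array against 2 controls with the spread taken from the other groups. The skeletal muscle median was then 0.04 and not called, and the ciliated (0.14), ribosomal (0.05) and cholesterol (0.03) calls were lost.

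Of the 13 calls in PM2.5 against control, 3 held whichever array was left out: cardiac muscle, B and plasma cell, and heat shock genes. The clock call was lost without control 1 (median -0.24) and the erythroid call without control 3 (0.20). The NRF2 call was lost without control 2, PM2.5 1 or PM2.5 2 (0.04 to 0.09). Club cell, ciliated and cholesterol calls were each lost without control 1, control 3, PM2.5 1 or PM2.5 2, at medians of 0.03 to 0.08, 0.04 to 0.11 and 0.03 to 0.07. The ribosomal call was lost without control 2, control 3, PM2.5 1 or PM2.5 3 (-0.017 to 0.05), and the mesothelial call without control 1, PM2.5 1 or PM2.5 2 (-0.018 to 0.022). The skeletal muscle call was lost without control 1, control 2 or PM2.5 3 (0.36 to 0.63), and the cell cycle call without control 3 (-0.013) or PM2.5 3 (0.04). The B and plasma cell median was 0.10 without PM2.5 1, with the call kept. Other medians that kept the call but moved by over 1.5 times were those of skeletal muscle without control 3, PM2.5 1 or PM2.5 2 (3.07, 2.78 and 0.86) and mesothelial markers without control 2, control 3 or PM2.5 3 (0.23, 0.21 and 0.48). So did those of cell cycle genes without control 1 or PM2.5 1 (0.25 and 0.26), ciliated markers without control 2 or PM2.5 3 (0.31 and 0.29), erythroid markers without PM2.5 2 or PM2.5 3 (0.35 and 0.13), ribosomal genes without control 1 or PM2.5 2 (0.07 and 0.023) and cholesterol genes without PM2.5 3 (0.08).

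Aryl hydrocarbon receptor target genes, which respond to combustion products, had a median of 0.14, and inflammatory cytokine genes one of 0.07, neither past the test. Aqp4, Trpv4, Rgs13, Tbx20 and Actc1 read 0.60 to 0.94 higher, and Spata31d1b, Skint10, Cma2, Cfap47 and Zscan4b read -0.59 to -0.91. Aqp4 read 0.40 without control 1, Cfap47 -0.34 without control 2, and Trpv4, Spata31d1b and Skint10 read 1.00, -0.41 and -0.51 without the 3 arrays. Limma called 0 genes, with a smallest adjusted p of 1.00, and 728 genes had an unadjusted p under 0.05 against 1109 by chance. Trend and robust eBayes and array weights called 0 too. Cxcl13, a B cell chemokine, was 1.84 higher with all arrays (adjusted p = 1.00) and passed when control 3 was left out (2.76, SE 0.28, adjusted p = 0.0395). That control read 11.1 for Cxcl13, level with the PM2.5 arrays (11.0 to 11.3), and the other controls read 8.12 and 8.55, so the call rests on leaving out the contrary control. Gm5622 (0.39 with all arrays) and Vnn3 (0.89), like Cxcl13 named after their values were seen, passed at 1.41 and 2.17 when the 3 arrays with squamous transcripts were left out, which leaves 1 PM2.5 array assumed to vary like the other groups.

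OVA+PM2.5 against control asked for the combined exposure. Clca1 was 4.14 (SE 1.01) higher, or 17.6-fold, Retnla 2.69 (SE 0.57) higher, or 6.44-fold, and Tff2 1.62 (SE 0.61) higher. Goblet cell and mucus genes rose, 17 of 18 higher with a median of 0.35, and Clca1 passed adjusted over the list alone, but of the 6 fits with 1 array left out only in that without OVA+PM2.5 3 (adjusted p = 0.91 with an estimated correlation). Retnla passed adjusted over the alternative macrophage list alone, though not without control 1, in a list that was not called. Club cell markers rose with a median of 0.10, and Aldh1a7 (0.51, SE 0.13), Gabrp (0.40, SE 0.12) and Cyp2b10 (0.29, SE 0.09) passed adjusted over the list alone, of which 0 did without control 1, control 3, OVA+PM2.5 2 or OVA+PM2.5 3 and 2 without OVA+PM2.5 1 (adjusted p = 0.91 with an estimated correlation). Heat shock and unfolded protein response genes rose with a median of 0.18, and Creld2, an endoplasmic reticulum stress gene, passed over the list alone at 0.54 (SE 0.13), though not when any 1 of the 6 arrays was left out (adjusted p = 0.91 with an estimated correlation). Collagen, elastin and matrix genes fell, 26 of 30 lower with a median of -0.16, with Col3a1 at -0.40 (SE 0.14) and Col1a2 at -0.34 (SE 0.15) and 0 past the test over the list alone (adjusted p = 0.91 with an estimated correlation). Without control 3, Col3a1 and Col1a2 read -0.21 and -0.18.

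B and plasma cell (median 0.17), ciliated (median 0.23), macrophage (median 0.18), NRF2 (median 0.12) and cardiac muscle lists (median 0.42) rose in OVA+PM2.5 lungs, each with an adjusted p = 0.91 with an estimated correlation. Skeletal muscle markers (median -1.80) and oxidative phosphorylation genes (median -0.11) fell, also with an adjusted p = 0.91 with an estimated correlation. Without control 3 the skeletal muscle median was -0.06 and not called, and oxidative phosphorylation genes were called in the opposite direction (median 0.08, adjusted p = 0.00391). The oxidative phosphorylation call was lost without OVA+PM2.5 2 (-0.10) or OVA+PM2.5 3 (-0.09). Of the 11 calls, those of collagen and club cell genes held whichever array was left out, with collagen at -0.10 and -0.09 without control 1 and control 3 and club cells at 0.16 and 0.19 without control 2 and control 3. Medians also moved by over 1.5 times with the call kept for oxidative phosphorylation without control 1 or control 2 (-0.21 and -0.20), ciliated markers without control 2 (0.41) and macrophage markers without OVA+PM2.5 3 (0.29). The goblet median was 0.58 without OVA+PM2.5 1 in OVA+PM2.5 against control. The goblet call was lost without OVA+PM2.5 2 (0.11), the heat shock call without control 2 or OVA+PM2.5 2 (0.12 and 0.16), and the B and plasma cell call without control 1 or OVA+PM2.5 1 (0.13 and 0.07). The macrophage call was lost without any 1 of 5 arrays other than OVA+PM2.5 3 (0.09 to 0.23), the NRF2 call without control 1, control 2, OVA+PM2.5 1 or OVA+PM2.5 2 (0.06 to 0.13), the ciliated call without control 1, control 3, OVA+PM2.5 2 or OVA+PM2.5 3 (0.11 to 0.23) and the cardiac call without control 1, control 2, OVA+PM2.5 1 or OVA+PM2.5 3 (0.24 to 0.55). The immediate early gene Nr4a1 passed adjusted over its list alone at -0.73 (SE 0.17), though not without control 1, control 2, OVA+PM2.5 2 or OVA+PM2.5 3, in a list that was not called. Apol11b read 2.02 (SE 0.75) higher, Smarca5-ps, Smim22, Zfp457, Cdr1, BC147527 and Reg1 read 0.63 to 0.70 higher, and Spata31d1b, Tas2r143, Gsdmc2, Esp16, Tfap2c, Cyp2j5, Fga, Uchl3 and Slco5a1 read -0.60 to -0.86. Among them, Smarca5-ps, Gsdmc2 and Esp16 had means of 2.3 to 3.9 in these groups, far below the array medians, and may lie at background. The same limit applies to low values of genes named in other comparisons. Examples are Csta3 (2.91), Skint10 (3.63) and Zscan4b (3.84) in PM2.5, Hsd3b1 (3.82) in OVA+PM2.5 and Mcpt4 (4.24) in OVA. Without control 3, Cyp2j5, Fga and Slco5a1 read -0.40, -0.40 and -0.37 in OVA+PM2.5 against control. Limma called 0 genes (smallest adjusted p 0.57), as did trend and robust eBayes and array weights, with 1014 genes at an unadjusted p under 0.05 against 1109 by chance.

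OVA+PM2.5 against OVA asked what particles added to sensitised lungs. Genes of inflammation, mucus and division were lower. The same 3 OVA arrays count positive in OVA against control and negative here. A list high on them for any reason therefore tends to rise there and fall here, even without an effect of particles. Inflammatory cytokine and NF-kB target genes fell, 23 of 25 lower with a median of -0.58, and Cxcl10 (-0.70, SE 0.14) and Ccl4 (-0.81, SE 0.21) passed adjusted over the list alone (adjusted p = 0.74 with an estimated correlation). Neither passed without OVA+PM2.5 2 or OVA+PM2.5 3, and Ccl4 also not without OVA 1 or OVA+PM2.5 1. Cell cycle genes (26 of 29 lower, median -0.31), interferon-stimulated genes (23 of 24 lower, median -0.27), alternative macrophage activation genes (16 of 16 lower, median -0.47) and goblet cell and mucus genes (17 of 18 lower, median -0.41) fell, each with an adjusted p = 0.74 with an estimated correlation. Collagen, elastin and matrix genes fell with a median of -0.18, Col3a1 reading -0.56 (SE 0.14) and Tnc -0.64 (SE 0.17) (adjusted p = 0.74 with an estimated correlation). Type 2 (median -0.20), eosinophil (median -0.41) and MHC class II lists (median -0.20) fell with an adjusted p = 0.74 with an estimated correlation, and neutrophil markers (median -0.21) with an adjusted p = 0.77 with an estimated correlation.

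Club cell (median 0.12), heat shock (median 0.19), endothelial (median 0.16), senescence (median 0.11) and adipose lists (median 0.71) rose in OVA+PM2.5 against OVA, each with an adjusted p = 0.74 with an estimated correlation, and Cyp2b10 passed adjusted over the club cell list alone at 0.43 (SE 0.09). Mcpt4, higher at a mean of 5.29 against 4.24, passed over the mast cell list alone, though not without OVA+PM2.5 1 or OVA+PM2.5 2, in a list that was not called. Pwwp3b, Kcnn3, Vstm2a, Ms4a4d and S100z read 0.62 to 0.82 higher, and Plac8 and Oas1g read -0.83 and -1.12, or -0.52 and -0.69 without OVA 1. Without OVA 2, which had the highest Chil4 (12.4) and Mmp12 (11.7) of all arrays, the medians of the inflammatory, eosinophil and type 2 lists were 0.08, 0.01 and 0.03, and 6 lists were called instead of 15. Those of collagen and cell cycle genes held whichever array was left out, the latter at -0.18 without OVA 1. Without OVA 2 the goblet (-0.23), alternative macrophage (-0.08) and MHC class II (-0.10) calls were lost as well, and without OVA 1 the interferon-stimulated call (0.03). Type 2 and eosinophil calls were also lost without OVA+PM2.5 3 (-0.21 and -0.36). Club cell calls were lost without OVA 2 or OVA+PM2.5 3 (both 0.08), the heat shock call without OVA 1, OVA 3 or OVA+PM2.5 2 (0.03 to 0.16), and the adipose call without OVA 2, OVA 3 or OVA+PM2.5 2 (0.44 to 0.57). The endothelial call was lost without OVA 1, OVA 2, OVA+PM2.5 1 or OVA+PM2.5 3 (0.12 to 0.17), the neutrophil call without OVA 1, OVA 2, OVA+PM2.5 2 or OVA+PM2.5 3 (-0.14 to -0.01), and the senescence call without any 1 of the 6 arrays (0.10 to 0.20). With the replicate number as a block on all 12 arrays the senescence call was lost too (adjusted p = 0.0642), and with the block on these 6 arrays alone it was kept (adjusted p = 0.0421). Medians that kept the call but moved by over 1.5 times were goblet -0.81, -0.23 and -0.70 without OVA 3, OVA+PM2.5 1 and OVA+PM2.5 2, and type 2 -0.43, -0.50 and -0.35 without OVA 1, OVA 3 and OVA+PM2.5 2. They included alternative macrophage genes without OVA 1 or OVA 3 (-0.74 and -0.78), MHC class II genes without OVA 1 or OVA 3 (-0.11 and -0.36), neutrophil markers without OVA 3 or OVA+PM2.5 1 (-0.54 and -0.72) and inflammatory genes without OVA 3 (-0.93). Without OVA 2 the interferon-stimulated and heat shock medians were -0.46 and 0.32, and club cell medians were 0.07 and 0.08 without OVA 3 and OVA+PM2.5 2. Limma called 0 genes (smallest adjusted p 0.41), as did trend and robust eBayes and array weights, with 1611 genes at an unadjusted p under 0.05 against 1109 by chance.

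OVA+PM2.5 against PM2.5 asked what sensitisation did under particles. Clca1 was 3.61 (SE 1.01) and Retnla 2.24 (SE 0.57) higher, and Glycam1 was 4.27 lower (log2 fold change -4.27, SE 0.77), with Timd4 at -1.01 (SE 0.21) and Pla2g2d at -0.71 (SE 0.16). The same 3 PM2.5 arrays count positive in PM2.5 against control and negative here. The lower values of Glycam1, Timd4 and Pla2g2d are therefore not separate from their higher values there. Mean Glycam1 was 6.26 in control, 6.73 in OVA, 10.2 in PM2.5 and 5.90 in OVA+PM2.5. Mean Timd4 was 6.50, 6.41, 7.35 and 6.34 in the same order. Htr2a, Csta2 and Csta3 read 0.61 to 0.73 higher (Csta3 0.48 without the 3 arrays with squamous transcripts), and Tfap2c and Hsd3b1 read -0.81 and -0.60. The goblet and alternative macrophage lists were not called in OVA+PM2.5 against PM2.5 (medians 0.28 and 0.13). Retnla passed adjusted over the latter list alone, though not without PM2.5 1, PM2.5 3 or OVA+PM2.5 2. Collagen, elastin and matrix genes fell, 23 of 30 lower with a median of -0.19, as did oxidative phosphorylation genes (median -0.16), cardiac muscle (median -0.22) and skeletal muscle markers (median -2.98), each with an adjusted p = 0.99 with an estimated correlation. PM2.5 2 and PM2.5 3, which with control 3 are the arrays high in Acta1 and Krt4, are 2 of the 3 arrays compared against here. With all 3 left out, and so 1 PM2.5 array kept, 9 lists were called instead of 4. Without OVA+PM2.5 1 or OVA+PM2.5 3 the lists called were 7 and 10, and the cardiac call was lost without PM2.5 2 (-0.07) or OVA+PM2.5 2 (-0.10). The cardiac median was -0.53, -0.42 and -0.14 without PM2.5 3, OVA+PM2.5 1 and OVA+PM2.5 3, that of oxidative phosphorylation -0.10 without PM2.5 3 and that of collagen -0.13 without OVA+PM2.5 1, with these calls kept. With the squamous list as a covariate the oxidative phosphorylation median in OVA+PM2.5 against PM2.5 was 0.060 and not called (adjusted p = 0.154). Limma called 0 genes (smallest adjusted p 0.27), as did trend and robust eBayes and array weights, with 945 genes at an unadjusted p under 0.05 against 1109 by chance.

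The interaction compared the OVA effect under particles with that in filtered air. It takes the OVA arrays with the opposite sign to OVA against control, so its calls are not separate evidence. It was negative for cell cycle (median -0.47), goblet (median -0.54), alternative macrophage (median -0.48), inflammatory (median -0.75), interferon-stimulated (median -0.29) and collagen lists (median -0.17), each with an adjusted p = 0.73 with an estimated correlation. Cxcl10 passed adjusted over the inflammatory list alone at -1.08 (SE 0.20), though not without the 3 arrays with squamous transcripts. Mcpt4 passed over the mast cell list alone, in a list that was not called, and likewise not without these arrays. Its group means were 5.56 in control, 4.24 in OVA, 5.08 in PM2.5 and 5.29 in OVA+PM2.5. In all, 14 lists were called, 12 negative and 2 positive, and 0 with an estimated correlation. Calls of goblet, alternative macrophage, cell cycle, endothelial and erythroid lists held whichever array was left out. Their medians moved by over 1.5 times for goblet genes without OVA 2, OVA 3, PM2.5 3 or OVA+PM2.5 2 (-0.29, -0.84, -0.85 and -0.83) and for alternative macrophage genes without OVA 2 or OVA 3 (-0.27 and -0.78). The same holds for cell cycle genes without control 3 (-0.31), endothelial markers without control 1 (0.15) and erythroid markers without PM2.5 2 (-0.49). Without OVA 2 the inflammatory call was lost (0.02), without OVA 1 the interferon-stimulated call (-0.03) and without control 2 the collagen call (-0.09). These medians also moved, with the call kept, to -1.13 for inflammatory genes without OVA 3, to -0.49 and -0.44 for interferon-stimulated genes without OVA 2 and OVA 3, and to -0.30 for collagen without control 3. Without the 3 arrays with squamous transcripts, which leaves 1 PM2.5 array and 2 controls, the cell cycle median was -0.06 and its call was lost. Ms4a4d (1.08, SE 0.20), S100z (1.02, SE 0.22), Catspere2, Kcnn3 and Smim4 were positive, and Trpv4 (-1.13, SE 0.25), Drd1, Kel and Krtap5-5 negative. Limma called 0 genes (smallest adjusted p 0.92), as did trend and robust eBayes and array weights, with 1082 genes at an unadjusted p under 0.05 against 1109 by chance.

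Averaged over both air conditions, Retnla was 3.02 (SE 0.40) and Clca1 4.48 (SE 0.71) higher in animals with OVA, with adjusted p of 0.27 and 0.31 over all genes and both past the test adjusted over their lists alone. Goblet cell and mucus genes rose, 18 of 18 higher with a median of 0.57 and 9 past the test over the list alone (adjusted p = 0.73 with an estimated correlation). Of the 9, 4 passed without control 2, 8 without PM2.5 1, only Clca1 without control 1, control 3, OVA 1, OVA 2, PM2.5 2, PM2.5 3 or OVA+PM2.5 2, and 0 without the 3 arrays with squamous transcripts. Rnase2a (4.16, SE 1.07), Ms4a4a and Htr2a were higher, and Col17a1 and Ano5 read -0.76 and -1.18. Ano5 read 7.09 to 8.40 on control 3, PM2.5 2 and PM2.5 3 and 5.45 to 5.76 on the other 9 arrays. Without the 3 arrays Col17a1 and Ano5 read -0.29 and -0.15, and Ano5 read -0.73 without control 3. Averaged over sensitised and unsensitised animals, heat shock (median 0.18), B and plasma cell (median 0.12) and club cell lists (median 0.19) rose with PM2.5, each with an adjusted p = 0.75 with an estimated correlation, and Cd79b (0.28, SE 0.06) and Cyp2b10 (0.27, SE 0.07) passed over their lists alone. Cd79b did not without OVA 1 or OVA+PM2.5 1, and Cyp2b10 not without control 1, control 3, OVA 1, OVA 3, PM2.5 1, PM2.5 2 or OVA+PM2.5 2. In the clock list, which was not called, 2 higher and 4 lower members passed over the list alone. Of these 6, 0 passed without OVA 1 or the 3 arrays, 2 without control 2, OVA 2, OVA+PM2.5 2 or OVA+PM2.5 3 and 3 without control 1, control 3 or PM2.5 3. For the averages, 19 and 12 lists were called, and 0 of them with an estimated correlation. Of these, 11 and 6 were called whichever array was left out. The 11 were goblet, type 2, alternative macrophage, neutrophil, inflammatory, macrophage, MHC class II, cell cycle and interferon-stimulated lists, which rose, and oxidative phosphorylation (median -0.15) and skeletal muscle lists (median -2.28), which fell, each with an adjusted p = 0.73 with an estimated correlation. Without OVA 2, of these 11 the type 2 median was 0.12, alternative macrophage 0.23, inflammatory 0.11, macrophage 0.17 and MHC class II 0.11. Interferon-stimulated genes were at 0.09 without OVA 1, neutrophil markers at 0.12 without OVA+PM2.5 1, and cell cycle, oxidative phosphorylation and skeletal muscle lists at 0.08, -0.06 and -1.34 without control 3. Control 3, PM2.5 2 and PM2.5 3, the arrays high in Acta1, are all from animals without OVA, and without them the skeletal muscle (-0.04), oxidative phosphorylation (-0.0014) and MHC class II (0.11) calls were lost and 12 lists were called instead of 19. With the squamous list as a covariate the oxidative phosphorylation median in the OVA average was 0.020 and not called. The 6 were the 3 lists named with PM2.5, NRF2 targets (median 0.09), cardiac muscle (median 0.55) and collagen (median -0.09), the last of which fell, each with an adjusted p = 0.75 with an estimated correlation. Of these, NRF2 and heat shock medians were 0.03 and 0.11 without OVA 3, the club cell median 0.09 without PM2.5 1, and B and plasma cell and collagen medians 0.17 and -0.13 without control 2. Limma, trend and robust eBayes and array weights called 0 genes for either, with 1366 and 1173 genes at an unadjusted p under 0.05 against 1109 by chance.

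**Figure D3:**
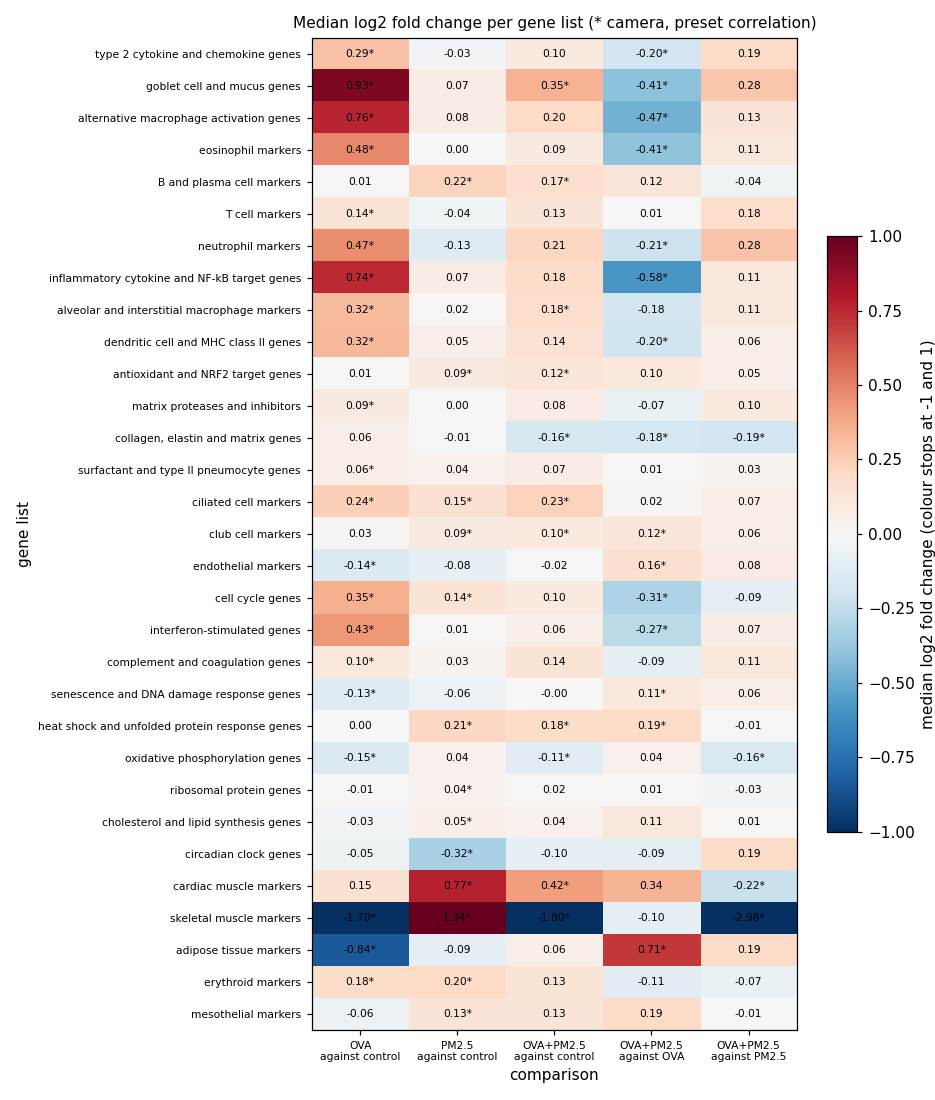
Median log2 fold change of the 31 gene lists (vertical axis) called in at least 1 of 5 comparisons (horizontal axis); colour and number give the median and an asterisk a call by camera at the preset correlation. The goblet list reads 0.93 in OVA against control and 0.35 in OVA+PM2.5 against control; 0 calls remained with an estimated correlation.

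Across 22180 genes, the OVA effect in filtered air and under particles, from separate arrays, correlated at r = 0.47 (Spearman's rho 0.09), where 8 of 100 random assignments of the arrays gave a value as large. Genes are not independent replicates, the random assignments took no account of the replicate numbers, and r was -0.03 without control 3. The PM2.5 effect with and without OVA correlated at r = 0.02 (rho 0.03), and 62 of 100 random assignments gave a value as large.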

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

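Tests of the squamous and clock patterns, and that of the Xist probe set, were chosen only after the results were seen. The test on genes that escape X inactivation and the counts over other splits of the arrays were set before their results were seen.

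The OVA effect differed between filtered air and particles for 14 lists by the interaction test, a difference lost in each with an estimated correlation. The medians were -0.28 for type 2 genes, -0.54 for goblet and mucus genes, -0.48 for alternative macrophage genes, -0.28 for eosinophil markers, -0.75 for inflammatory genes, -0.27 for MHC class II genes and -0.17 for collagen and matrix genes. They were 0.25 for endothelial, -0.47 for cell cycle, -0.29 for interferon-stimulated, -0.43 for cardiac muscle, -1.30 for skeletal muscle, 0.75 for adipose and -0.30 for erythroid lists. Without OVA 2 the type 2 median was 0.054 and the eosinophil median 0.012, and these calls and those of MHC class II, cardiac, skeletal muscle and adipose lists were lost without more than 1 of the single arrays. Where calls were kept, medians moved by over 1.5 times to -0.29 for goblet and -0.27 for alternative macrophage genes without OVA 2, to -0.31 for cell cycle genes without control 3, to 0.15 for endothelial markers without control 1 and to -0.17 for MHC class II genes without OVA 1. Larger medians, among them -2.96 for skeletal muscle without control 3 and -0.76 for cardiac muscle without OVA 2, came from leaving out others. Without the 3 arrays with squamous transcripts the adipose median was -0.25 and not called, with 1 PM2.5 array left. In 11 named genes the OVA arrays lay wholly on one side of the controls and the OVA+PM2.5 arrays wholly on the opposite side of the PM2.5 arrays. Their interaction was positive in Ms4a4d (1.08), S100z (1.02), Colgalt2 (0.92), Kcnn3 (0.84), Smim4 (0.77), Catspere2 (0.72) and Pwwp3b (0.56). It was negative in Trpv4 (-1.13), Drd1 (-0.61), Krtap5-5 (-0.60) and Kel (-0.60), and limma's interaction test was not passed by any of these 11 (adjusted p = 0.92), most of which were named for their interaction. Over all genes, 9.27% had no overlap in OVA against control and 12.5% in OVA+PM2.5 against PM2.5, where 10% are expected by chance.

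Squamous epithelium and skeletal muscle transcripts were high on control 3, PM2.5 2 and PM2.5 3. Particle exposure as the whole cause is argued against by control 3, whose squamous list mean lay 3.26 log2 units above the higher of the other 2 controls. The median over all genes was -0.051 on the 3 arrays relative to the other 9, while the squamous list differed by 2.85. RMA holds array medians close together, so this cannot decide whether whole arrays were shifted before it. A candidate explanation is tissue of the oesophageal kind in these samples: 14 of 18 squamous genes not among those first noticed were higher on all 3 arrays than on each of the other 9, and Krt4 and Krt13 reached 13.5 and 11.4. Nothing here separates that tissue from another squamous and muscular one.

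Xist was high and Y-linked transcripts low on 5 of 12 arrays described as male. An artifact of the Xist probe set is argued against by the Y-linked genes, whose lowest mean on the 7 arrays lay 1.51 above the highest on the 5. Female tissue is a candidate explanation: the mean of Kdm6a, Kdm5c and Ddx3x, which escape X inactivation, was 0.40 higher on the 5 arrays (exact permutation test over 792 splits, two-sided p = 0.0013, the smallest it can give). Eif2s3x, also set for that test, was not measured, since its probe sets carry more than 1 symbol. Whether the animals, the samples or the labels were exchanged was not tested, and control 1, with low Xist (5.56) and a Y-linked mean of 6.23, lay apart from both kinds.

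The clock genes differed between PM2.5 and control arrays. A difference in clock phase between single animals, as from the time of day of collection, is a candidate explanation: within groups the mean of Npas2, Arntl, Clock and Nfil3 and that of Dbp, Per1, Nr1d1 and related targets moved oppositely (r = -0.82, rho = -0.83, n = 12, r = -0.75 without the 2 farthest arrays). With the same-numbered OVA and OVA+PM2.5 arrays kept together, the permutation p over 216 orders was 0.037 for both (adjusted p = 0.11 over 3 relations). Whether squamous tissue adds to it stays open, since the shift of 1.25 between the groups was 0.65 without the 3 arrays, midway between none and all of it within the SD of 0.22 between control animals, with 1 PM2.5 array left. An effect of particles cannot be told apart from phase here: the shift was 0.61 in OVA+PM2.5 against OVA, and collection times were not given in the sources used here. Those groups overlapped, but the score was higher with particles within 3 of 3 same-numbered pairs (by 0.12 to 1.07), where a sign-flip test cannot give a p under 0.25.

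Other splits of the arrays were counted for each number of calls. For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. With 0 genes in the real split, every split gives as many (10 of 10 in all 5 such comparisons), so the gene counts say nothing of chance. They had highest other values of 0 for OVA against control, 341 for PM2.5 against control, 0 for OVA+PM2.5 against control, 9 for OVA+PM2.5 against OVA and 0 for OVA+PM2.5 against PM2.5. The 341 genes came from setting control 3, PM2.5 2 and PM2.5 3 against control 1, control 2 and PM2.5 1, which points to the squamous structure of the samples. As many lists came from 4 of 10 splits for OVA against control (21 real, highest other 24), 3 for PM2.5 against control (13, 19), 5 for OVA+PM2.5 against control (11, 17), 6 for OVA+PM2.5 against OVA (15, 21) and 10 for OVA+PM2.5 against PM2.5 (4, 13). For OVA+PM2.5 against OVA, 4 splits part all 3 same-numbered pairs, and as many lists came from 3 of these (15, 17).

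Over 100 splits, 100 of 100 gave as many genes as the real 0, which again says nothing of chance. The highest other values were 130, 5 and 197 for the interaction, the OVA average and the PM2.5 average. The splits with 130 and 197 genes set control 3, PM2.5 2 and PM2.5 3 all on the same side, which points to the same structure. For lists, chance is not excluded: as many came from 69 splits for the interaction (14 real, highest other 25), 27 for the OVA average (19, 25) and 82 for the PM2.5 average (12, 31). These splits were drawn without regard to the replicate numbers.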

How the results depend on the processing

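Alternatives that leave out the 3 arrays with squamous transcripts, take those transcripts or Xist as a covariate, or fit the OVA and OVA+PM2.5 arrays alone with a block, were chosen after seeing the data. Counts of called genes were 0 in the comparisons run (5 for the compared groups alone, 8 otherwise) under the planned settings that keep all arrays, except an unadjusted p under 0.05 with a 1.5-fold change, which gave 207, 79, 84, 130, 129, 297, 190 and 17 genes in the order of the comparisons above. Leaving out single arrays gave 0 to 1 genes for OVA against control and for PM2.5 against control, and 0 for the other 6. Without the 3 arrays, 2 genes were called for PM2.5 against control and 2 for the interaction, with 1 PM2.5 array left. With an estimated correlation and with fry, 0 lists were called in all 8 comparisons. List counts moved to 7 for OVA+PM2.5 against control with the higher-mean genes, to 8 for PM2.5 against control with quantile normalization, and to 9 for OVA+PM2.5 against PM2.5 and 12 for the OVA average without the 3 arrays. They moved to 5 for OVA+PM2.5 against control and 9 for OVA+PM2.5 against PM2.5 with the squamous covariate. Single list calls lost with the higher-mean genes numbered 17: in OVA against control T cell and senescence; in OVA+PM2.5 against control macrophage, NRF2, ciliated and cardiac; in OVA+PM2.5 against OVA type 2, club cell, endothelial, senescence, heat shock and adipose; in the interaction type 2 and adipose; and in the averages MHC class II, ciliated and mesothelial. Quantile normalization lost 14: senescence in OVA against control, ciliated, club cell, ribosomal, cholesterol and mesothelial in PM2.5 against control, macrophage and NRF2 in OVA+PM2.5 against control, eosinophil, neutrophil, endothelial and senescence in OVA+PM2.5 against OVA, eosinophil in the interaction and cardiac in the OVA average. The Xist covariate lost 9: macrophage, ciliated and heat shock in OVA+PM2.5 against control, neutrophil and heat shock in OVA+PM2.5 against OVA, cardiac in OVA+PM2.5 against PM2.5, in the interaction and in the OVA average, and ciliated in the OVA average. The squamous covariate lost 21 and reversed 4. The 21 were T cell, surfactant, ciliated, complement, oxidative phosphorylation and skeletal muscle in OVA against control, skeletal muscle in PM2.5 against control and in the interaction, and B cell, macrophage, NRF2, ciliated and skeletal muscle in OVA+PM2.5 against control. The others were T cell, MHC class II, collagen, complement, cardiac, skeletal muscle and adipose in the OVA average and cell cycle in the PM2.5 average. A call lost here does not show that squamous tissue made it, since some medians hardly moved: that of macrophage markers in OVA+PM2.5 against control was 0.17 with the covariate and 0.18 without. Leaving out single arrays gave 8 to 15 lists for PM2.5 against control, 7 to 10 for OVA+PM2.5 against control, 6 (without OVA 2) to 20 for OVA+PM2.5 against OVA, 5 to 10 for OVA+PM2.5 against PM2.5 and 9 to 25 (without OVA 3) for the PM2.5 average. The replicate block called 0 genes in all 8 comparisons and 7 lists for OVA+PM2.5 against PM2.5 instead of 4. On the OVA and OVA+PM2.5 arrays alone it called 0 genes and 19 lists. Besides the senescence call given with its comparison, the block changed no other call for OVA+PM2.5 against OVA among the 15 lists called there. In the other 5 pairs of groups the rule for pairing was not met. Still, 10 of 12 arrays correlated best with an array of their own number, so a link by number is not excluded there. Between control and PM2.5, r was 0.65 for control 3 and PM2.5 3, both with squamous transcripts. It was 0.53 for control 1 and PM2.5 1, but also 0.50 for control 2 and PM2.5 1.

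Medians that reversed without the 3 arrays were those of T cell markers (-0.0028), oxidative phosphorylation (0.029) and skeletal muscle (0.066) in OVA against control, cell cycle in PM2.5 against control (-0.23), oxidative phosphorylation in OVA+PM2.5 against control (0.076) and adipose markers in the interaction (-0.25). With the squamous covariate, oxidative phosphorylation reversed in OVA+PM2.5 against control (0.023), against PM2.5 (0.060) and in the OVA average (0.020), and ciliated markers in the OVA average (-0.0015). Without control 3, T cell (-0.0028 to 0.35 over single arrays left out), oxidative phosphorylation (-0.25 to 0.029) and skeletal muscle lists (-2.60 to 0.066) reversed in OVA against control, as did oxidative phosphorylation (-0.21 to 0.076) and the test of skeletal muscle (-2.66 to -0.056) in OVA+PM2.5 against control. Without OVA 2, type 2 (-0.50 to 0.032), eosinophil (-0.59 to 0.014) and inflammatory lists (-0.93 to 0.084) reversed in OVA+PM2.5 against OVA, type 2 genes in the interaction (-0.48 to 0.054) and inflammatory genes in the PM2.5 average (-0.40 to 0.047). Without OVA 1, interferon-stimulated genes reversed in that average (-0.19 to 0.020). Agreement of the OVA effect was 0.093 by Spearman, -0.032 without the 3 arrays and -0.034 to 0.60 without single arrays, the lowest without control 3. Agreement of the PM2.5 effect was -0.0026 without the 3 arrays and -0.035 to 0.094 without single arrays, negative without control 2, control 3, OVA 2, OVA 3 or PM2.5 2. Where an alternative does not itself show the cause by leaving out arrays, the cause was not tested. Genes named by the rule kept their direction and did not pass the test over all genes under the alternatives run for them, while Junos, Cxcl13, Gm5622 and Vnn3, outside that rule, passed as given with their comparisons. Signal over background was not recorded in the values.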

Other observations

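The tests here were chosen only after the results were seen. The response to OVA varied between animals: Chil4, a chitinase-like protein of allergic airways, read 7.26, 12.4 and 4.72 on OVA 1, OVA 2 and OVA 3, and Mmp12, a macrophage elastase, 7.16, 11.7 and 7.23. Over the 6 arrays of OVA-treated animals, the goblet and alternative macrophage list means went together (r = 0.84, rho = 0.89, r = 0.94 without the 2 farthest arrays). If the numbers pair these arrays, which is not established, there are 3 pairs. The permutation p over their 6 orders was then 0.17, the smallest it can give (adjusted p = 0.25 over 3 relations). These lists rising together in the same animals may reflect the strength of each animal's response, a hypothesis the 3 pairs do not settle. OVA 2 was also the only OVA array with high Xist (12.0, against 5.11 and 5.02 on OVA 1 and OVA 3). These values do not separate that difference from the strength of its response.

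Glycam1 read 9.19, 9.48 and 11.8 on the PM2.5 arrays, 5.99 to 6.77 on the controls, 8.55, 5.66 and 5.99 on OVA 1, OVA 2 and OVA 3, and 5.89 to 5.91 on the OVA+PM2.5 arrays. A candidate explanation is lymph node or high endothelial venule tissue in the PM2.5 lungs, carried over or formed there. The other 8 genes of a lymph node list written after Glycam1 was seen had a median of 0.33 in PM2.5 against control, 7 of 8 higher. The unadjusted camera p was 4.3e-06, and 0.0014 with an estimated correlation. Because the list was written after values of these arrays were seen, this test is not separate evidence for that source. It also does not tell dissection from exposure. Cd79b, Fcer2a and Cr2 are on this list and on that of B and plasma cells, which was already called higher in PM2.5 against control.

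Probe sets without a single gene symbol, 17634 beside the control probe sets, gave 0 calls in limma in all 8 comparisons, with 681 to 1021 at an unadjusted p under 0.05.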
